A study of Drosophila melanogaster with 3 samples.

How the data were processed

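Testes of 3rd instar larvae of a wMel-infected and a tetracycline-treated Drosophila line were profiled on 3 two-colour arrays, each with 1 infected sample labelled with Cy5 and 1 control sample labelled with Cy3, per the labels. Total RNA was extracted with Trizol and labelled by DNA synthesis from reverse-transcribed cRNA, per the labels' protocols. No array carried the dyes the other way round. Array 3 is replicate 3 by its label, while its file header numbers the infected sample 3 and the control sample 5. Arrays were scanned and read with LuxScan, per the file headers, and its version is not given in the sources used here.

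The deposited scanner files hold, for each spot, the mean and median intensity of the spot and of its local background in both channels, per the file headers on a linear scale and without background subtraction in the columns used. They also hold the log10 ratio of the spot means, infected over control, which the deposited value table of the series repeats with a largest difference of 0. The log10 ratio equals that of the deposited intensities within 0.00507, so it was neither background-corrected nor normalized. Its median over all spots was -0.364, -0.340 and -0.395 on arrays 1, 2 and 3. A column of spot flags, deposited with a positive and a negative value whose meaning is not stated, was negative for 53.9%, 49.9% and 47.9% of probe spots. The negative value was taken as a flag, in an alternative only.

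The analysis used R 4.3.3 and limma 3.58.1, and figures were drawn with matplotlib. Background was corrected on the spot mean and background median with normexp and an offset of 50, fitted on all spots. Ratios were normalized within each array by loess with a span of 0.3, with spots other than fly probes at weight 0, and the 2 spots of a probe were averaged. A probe counted as above background where its background-subtracted intensity exceeded the 95th percentile of the 1246 spots named Empty, Blank or 50%DMSO on that array and channel, and probes above it in no channel of any array, 355 in all, were left out of the test. The log2 ratio of infected over control was tested against 0 with lmFit and eBayes, with Benjamini-Hochberg adjustment and a threshold of 0.05, two-sided. The duplicate spots of a probe differed with an SD of 0.19, 0.15 and 0.17 on the log2 scale. An exact sign-flip test on 3 arrays cannot give a two-sided p below 0.25, so single probes rest on limma's shared variance.

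The array pairs each infected sample with a control sample, and the model of the ratio keeps that pairing. After scaling between arrays, the deviations of the 2 channels of one array from their group means correlated with r of 0.43, 0.46 and 0.41 across probes, and those of different arrays with r between -0.31 and -0.06.

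The gene lists and the genes to be named were fixed before the data were examined. The rule was to name the 12 genes with the largest positive and the 12 with the largest negative mean ratio among those past the threshold with the same sign on all arrays, members of each list that passed, and every measured gene linked to cytoplasmic incompatibility. It could not be followed, because the probes carry numbers that the files do not pair with genes and 0 of which matched the gene table used here. In each direction the 2 probes with the largest mean ratio among those past the threshold with the same sign on all 3 arrays were named by number, and the 12 genes named on the array were fitted in limma as a set of their own, a test added after the files were seen. Their symbols were looked up in that gene table: Hsp60 matches 3 current genes and RpS19 matches 2, eIF-4a is eIF4A today, and the other names are current. None of the 34 lists had the 5 named genes set as the minimum for camera, so no set test was run. Spots Y1 to Y8 and Hex, whose content the labels do not give, were left out of the tests.

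The procedure was tested on simulated data for the comparison of infected over control, with the real intensities and backgrounds of 14238 probes, 200 of them changed. Of 50 probes changed by each fold, 4% were recovered at the smallest change simulated, 0.32 on the log2 scale, which is below the median change of the called probes, and 44% were recovered at 1.5-fold, 98% at 2-fold and 100% at 3-fold, and 9 of the 132 calls were of unchanged probes. The simulation held no position or dye effects. It gave 132 calls against 3903 in the data, so the Benjamini-Hochberg adjustment was stricter there. Spot noise was also added to a variance that already held part of it. The rates of recovery and of false calls therefore do not carry over to the real test. Alternatives covered background correction, normalization within and between arrays, the deposited ratios, filters, flags, the variance model, pairing, a fold threshold and leaving out each array; correction by print block and row, centring on spots Y1 to Y4, the centred deposited ratios and the joint fit of named genes with probes were added after the data were seen.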

Results

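Gene expression in the testes of 3rd instar Drosophila melanogaster larvae was compared between larvae that carried Wolbachia and larvae that did not. Wolbachia is a maternally inherited intracellular bacterium, and wMel is a strain of it found in D. melanogaster. The control line had been cured with the antibiotic tetracycline and kept for several generations. The series held 3 infected and 3 control testis samples, grown and dissected independently per its design text, and each of the 3 two-colour oligonucleotide arrays carried 1 infected sample in the Cy5 channel and 1 control sample in the Cy3 channel. The question the design poses is which transcripts differ in level between infected and uninfected larval testes.

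Each array was printed in 48 blocks. It held 29186 spots of 14593 fly probes that the files identify by number only, with 2 spots each, and 12 fly genes that are named, with 96 spots each. After subtraction of the local background, the median spot intensity in the infected channel was 369, 440 and 340 on arrays 1, 2 and 3, and in the control channel it was 588, 741 and 682. Of the 14593 probes, 14238 were above the level of spots named Empty, Blank or 50%DMSO in at least 1 channel of at least 1 array, and 10501 in both channels on all 3 arrays. The number of arrays, 3, limits the precision of every ratio below.

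Among the 12 named genes, 6 differed between infected and control testes, 4 higher and 2 lower. The sign of the mean ratio followed brightness across the 12 genes. Genes with a log2 level from 12.6 (Gapdh1) to 13.5 (eIF-4a) in the infected channel all had a mean ratio above 0. Genes from 7.9 (RpS25) to 10.5 (Hsp70Bc) all had one below 0. The spots of these genes had weight 0 in the loess, and whether a remaining trend with intensity gave this split was not tested. Gapdh1, a glycolytic enzyme, was higher in infected testes by 0.56 ± 0.39 on the log2 scale (SD, n = 3, 1.48-fold). RpS19, a protein of the small ribosomal subunit, was higher by 0.39 ± 0.09 (1.31-fold), eIF-4a, the RNA helicase of translation initiation, by 0.37 ± 0.15 (1.29-fold), and RpL9, a protein of the large ribosomal subunit, by 0.25 ± 0.03 (1.19-fold), each on all 3 arrays. CG13334 fell by 0.61 ± 0.17 in infected testes (SD, n = 3), to a level 1.53-fold below the control. RpS25, another protein of the small ribosomal subunit, had a log2 ratio of -0.28 ± 0.08, below 0 on all 3 arrays, but turned to 0.16 when each array was centred on its spots Y1 to Y4.

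In limma's test with Benjamini-Hochberg adjustment over the 12 genes, the adjusted p was 0.0187 for CG13334, 0.0221 for RpS19, 0.0340 for eIF-4a, RpL9 and RpS25, and 0.0424 for Gapdh1. Fitted together with all probes, RpL9 (adjusted p = 0.0831) and RpS25 (adjusted p = 0.0609) did not pass and the other 4 did. Without array 2 all 6 calls were lost, with adjusted p between 0.121 and 0.202, and without array 3 the 5 calls other than that of CG13334 were lost, with adjusted p of 0.140 or 0.141 for 4 of them and 0.116 for RpS19. With both channels treated as unpaired samples, Gapdh1 (adjusted p = 0.0822) and RpL9 (adjusted p = 0.122) did not pass. Without flagged spots Gapdh1 (adjusted p = 0.0578) and RpS25 (adjusted p = 0.0519) did not pass, with the median of the repeated spots in place of their mean Gapdh1 did not pass (adjusted p = 0.0587), and centring on Y1 to Y4 ended the call of CG13334 (log2 ratio -0.18, adjusted p = 0.122).

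The sizes depended on the scaling. With median centring in place of loess the log2 ratio was 1.08 for Gapdh1, 0.95 for eIF-4a, 0.92 for RpS19, 0.79 for RpL9, -0.75 for CG13334 and -0.998 for RpS25, and with the deposited ratios, which are not centred, CG13334 was at -1.82 and RpS25 at -2.59. With these centred, Gapdh1, eIF-4a, RpS19 and RpL9 lay between 1.48 and 1.72, and centred on Y1 to Y4 between 0.68 and 1.00.

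The size of the Gapdh1 difference varied between arrays, with log2 ratios of 1.00, 0.42 and 0.26 on arrays 1, 2 and 3. RpL9 and RpS19 were closer between arrays, at 0.28, 0.24 and 0.21 for RpL9 and 0.33, 0.35 and 0.50 for RpS19. RpS19 matches 2 current genes, RpS19a and RpS19b, and the files do not tell which of them its oligonucleotide detects. CG13334 had log2 ratios of -0.71, -0.71 and -0.42. RpS25 was the dimmest of the 12 genes, with a background-subtracted intensity of 67.4 in the infected channel, where the limit set by the Empty, Blank and 50%DMSO spots lay between 46.6 and 58.3. The 50%DMSO spots had a log2 ratio of -0.21 ± 0.05 (SD, n = 3), and the Blank and Empty spots, which are the larger part of the 1246, had 0.03 ± 0.02 and 0.0022 ± 0.020. All spots of the 12 genes lay in the first row of each print block, and the fly probes nearest to them, in row 2, had median log2 ratios of -0.14, -0.15 and -0.18 on the 3 arrays.

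The other 6 named genes did not pass. The cytoskeletal genes Act42A, a cytoplasmic actin, and betaTub85D, the testis-specific beta-tubulin, had log2 ratios of 0.09 ± 0.17 and 0.06 ± 0.06 (SD, n = 3), both with a limma adjusted p of 0.439. Both passed with median centring in place of loess (0.65 and 0.64), centred on Y1 to Y4 (0.52 and 0.50) and with the centred deposited ratios (1.36 each), betaTub85D also with the deposited ratios as they are (0.19), while Act42A turned to -0.0070 without array 1. His3.3A, which encodes the replacement histone H3.3, had -0.15 ± 0.20, Nup154, a nuclear pore protein, -0.18 ± 0.08, and Hsp60, the mitochondrial chaperonin, -0.17 ± 0.11, and all 3 values turned positive when the arrays were centred on Y1 to Y4. The name Hsp60 matches 3 current genes, Hsp60A, Hsp60B and Hsp60C, and the files do not tell which of them its oligonucleotide detects. His3.3A passed with the deposited ratios (-1.04, adjusted p = 0.00206) and turned to 0.12 when these were centred. Nup154 passed in 6 and Hsp60 in 7 of 16 alternatives each, among them normalization of each print block by itself (adjusted p = 0.0460 and 0.0480). Hsp70Bc, a heat-inducible chaperone with near-identical copies in the genome, had log2 ratios of 0.66 on array 1, -0.55 on array 2 and -0.87 on array 3, and its mean of -0.25 ± 0.81, which turned to 0.13 with median centring (adjusted p = 0.528), did not pass (limma adjusted p = 0.463). It passed in opposite directions under 2 alternatives, at -0.71 without array 1 (adjusted p = 2.27e-05) and at 0.58 with the centred deposited ratios (adjusted p = 0.00250).

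**Figure D1:**
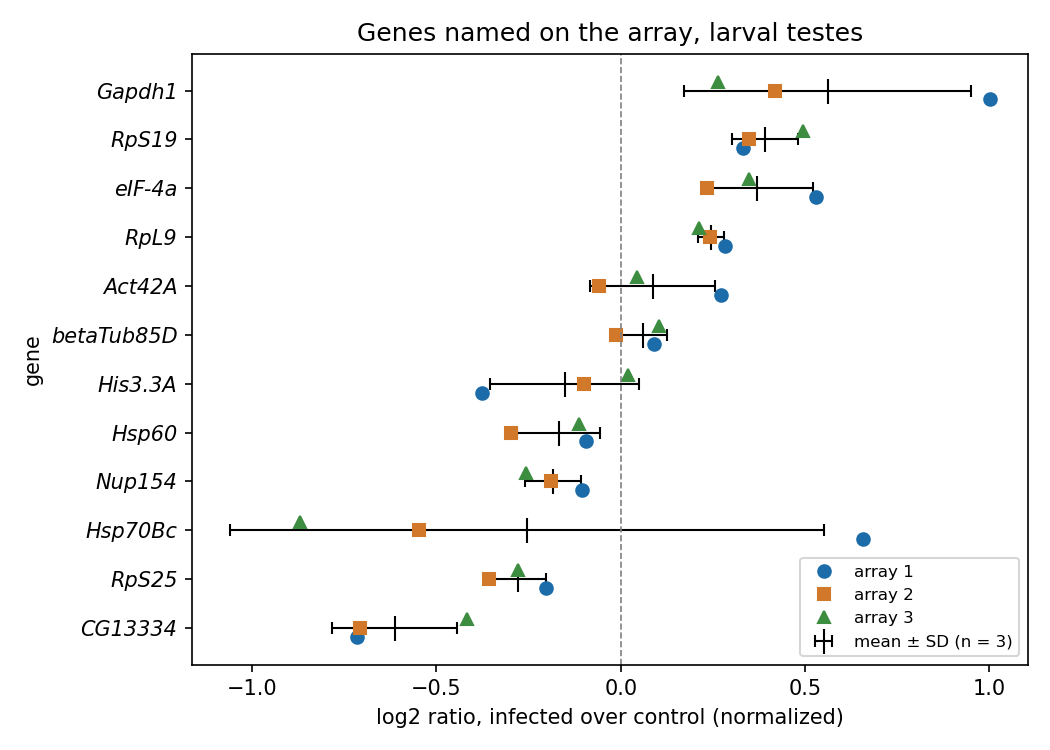
Log2 ratio of infected over control testes for each of the 12 named genes, with 1 symbol per array and a bar for the mean and SD of the 3 arrays. Gapdh1, RpS19, eIF-4a and RpL9 lie to the right of 0 on all 3 arrays, CG13334 and RpS25 to the left (RpS25 turns positive when arrays are centred on Y1 to Y4, as do the means of His3.3A, Nup154, Hsp60 and Hsp70Bc), and Hsp70Bc lies at 0.66 on array 1 and at -0.55 and -0.87 on the others.

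Of the 34 gene lists fixed in advance, 5 had a named member on the array, and none had the 5 named genes needed for a test of the list. Of the ribosomal proteins, RpL9 and RpS19 rose and RpS25 fell (reversed when centred on Y1 to Y4), all 3 also when adjusted over the list alone, whereas RpS19 alone passed when adjusted over all 14250 probes and genes. Of the glycolysis list, Gapdh1 rose under all 3 adjustments. Neither named member of the heat shock and chaperone list, Hsp60 and Hsp70Bc, passed adjusted over the list alone, and neither did betaTub85D and His3.3A, the named members of the list of genes linked to cytoplasmic incompatibility, the failure of embryos when Wolbachia-infected males mate with uninfected females. The list of late spermatid genes had betaTub85D as its 1 named member, which did not pass.

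Across all fly probes, 1989 of 14238 were higher and 1914 lower in infected testes (limma, Benjamini-Hochberg adjusted p under 0.05), so that 51.0% of the 3903 probes past the threshold were higher. Their differences were small: the median change was 1.39-fold, 552 probes were higher and 596 lower by at least 1.5-fold, and 79 were higher and 94 lower by at least 2-fold. Among probes past the threshold with the same sign on all 3 arrays, DM00016241 had the largest mean ratio, 2.83 ± 2.44 on the log2 scale (SD, n = 3, adjusted p = 0.0204), made up of 4.44 and 4.03 on arrays 1 and 2 and 0.03 on array 3. DM00016241 was above background on 2 arrays in the infected channel and on 1 array in the control channel, so the size of its ratio is uncertain. DM00008901 followed with 2.54 ± 1.98 (adjusted p = 0.0147), from 3.53, 3.81 and 0.26. DM00016241 and DM00008901 lost their calls with an intensity trend and robust variance estimate together (adjusted p = 0.267 and 0.236), with the channels unpaired (adjusted p = 0.130 and 0.164) and with the deposited ratios (1.20 and 1.29, adjusted p = 0.356 and 0.315). In the other direction, DM00004481 fell by 1.82 ± 0.21 (adjusted p = 0.000395) and DM00007984 fell by 1.63 ± 0.45 (adjusted p = 0.000910), each on all 3 arrays, though DM00007984 was at -0.41 with the deposited ratios centred on their median. The files do not pair these numbers with genes.

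**Figure D2:**
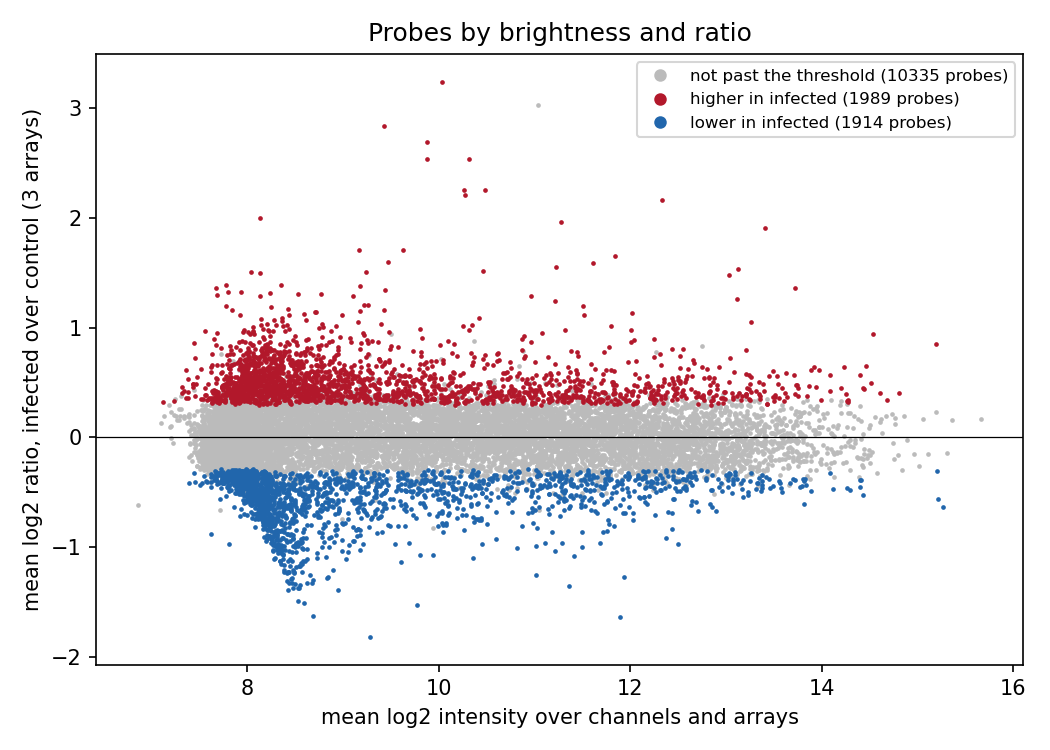
Mean log2 ratio of infected over control testes over the 3 arrays (vertical axis) against mean log2 intensity (horizontal axis) for the 14238 probes tested, each a point, with the 1989 higher probes in red and the 1914 lower ones in blue. Few points lie beyond a 4-fold difference, 10 of the higher and 0 of the lower probes past the threshold. Only 5 of these 10 had a ratio above 0 on all 3 arrays, DM00016241 and DM00008901 among them. Of these 5, DM00008901 was at 0.26 on array 3. DM00000494 had log2 ratios of 3.74, 3.47 and -0.58 on arrays 1, 2 and 3, and DM00016241 had 4.44, 4.03 and 0.03. Of all probes past the threshold, 12 did not have the same sign on all arrays.

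The ratios of the 3 arrays correlated across probes with Pearson r of 0.68, 0.59 and 0.70 for arrays 1 and 2, 1 and 3, and 2 and 3, where probes are not independent replicates. Of the probes tested, 8826 of 14238 had the same sign on all 3 arrays, where chance gives 25% for arrays with nothing in common. The arrays shared dye orientation and print layout, which can raise this share without any effect of infection. The split into higher and lower depended on the centring: the deposited ratios, which are not centred, gave 652 higher and 10409 lower, 5.89% higher, and centring on the spots Y1 to Y4, which shifted every log2 ratio by 0.44 on average, gave 8246 higher and 221 lower, 97.4% higher. Directions here are therefore relative to the bulk of the probes. With the 2 channels of an array treated as unpaired samples, the counts were 731 higher and 857 lower, and without array 2 they were 1002 and 884.

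Ratios also followed the position of the probe on the slide. The print block accounted for 15.1% of the variance of the mean log2 ratio, with block medians from -0.37 to 0.17 that correlated between arrays with r of 0.90 to 0.93. In rows 2 to 9 of the blocks 226 probes were higher and 1136 lower, and in rows 10 to 26 1763 were higher and 778 lower. In normalizations chosen after seeing the data, a curve for each print block left 1176 higher and 1070 lower, and a further curve for each row left 516 higher and 359 lower. Of the 3903 probes, 771 passed in the same direction under this last correction, 458 higher and 313 lower, and of the 173 that changed by at least 2-fold, 86 did. Of the probes named above, DM00008901, DM00004481 and DM00007984 passed under it and DM00016241 did not (adjusted p = 0.0590), although its log2 ratio of 2.77 was close to the 2.83 before. Because all arrays carried infected RNA in Cy5, a ratio shared by the 3 arrays holds both the infection and any dye preference of the probe. It also holds any position effect that the arrays share. All arrays compared the same lines, so any effect of the tetracycline treatment or of the generations kept since is in the ratio too. Dye preference, print row and the history of the lines cannot be told apart from the infection here. An effect of print block can be in part. The oligonucleotides of 4 dim genes, each present under one name in every block, followed the block medians of the other probes with a median r of 0.74. For the 8 brighter genes the median r was 0.16.

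**Figure D3:**
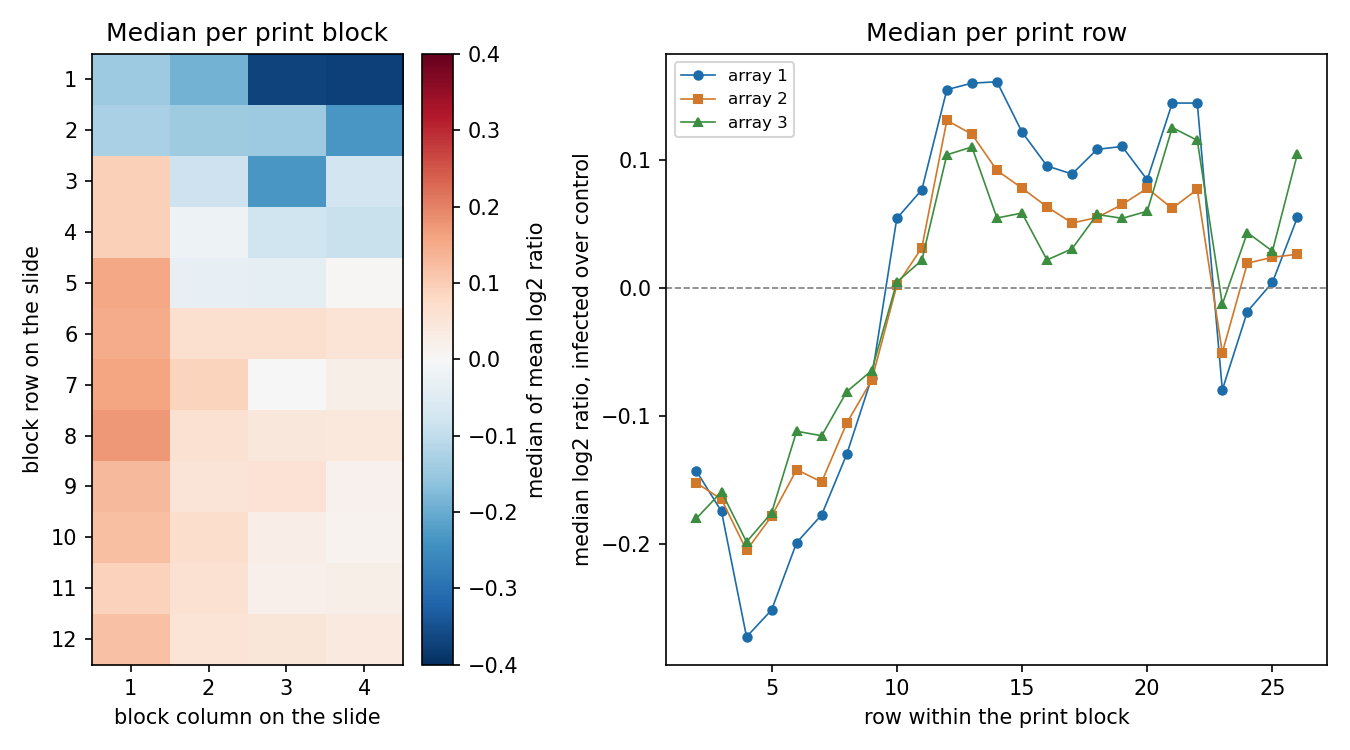
Left, median of the mean log2 ratio of infected over control in each of the 48 print blocks, at its place on the slide; right, median log2 ratio per row within the blocks, with 1 line per array. Block medians run from -0.37 to 0.17, and rows 2 to 9 lie below 0 on all 3 arrays.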

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

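Spots outside the comparison gave signal well above that of empty spots, which drew attention to them. The content of spots Y1 to Y8 and Hex is not given by the labels. Spots Y1, Y2, Y3 and Y4 had mean log2 ratios of infected over control of -0.57, -0.29, -0.43 and -0.46 over the 3 arrays. Those of Y5 and Y6 were -3.28 and 2.46, and those of Y7 and Y8 were -1.60 and 0.76. The mean of Y1 to Y4, -0.44, lay close to the midpoints of Y5 and Y6, -0.41, and of Y7 and Y8, -0.42. If these spots detect RNA added in set proportions, which the labels do not say, 0 would lie near these values, and with the arrays centred on Y1 to Y4 8246 probes were higher and 221 lower. Spots named Hex had a median signal of 61022 in the Cy3 channel and of 45.6 in the Cy5 channel, which is not above the background limit of 46.6 to 58.3, so their mean log2 ratio of -8.75 depends on the background correction and gives no size.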

How the results depend on the processing

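Alternatives by print block and row, the centred deposited ratios, the centring on Y1 to Y4, the joint fit and the median of spots were chosen after seeing the data. Against 1989 higher and 1914 lower probes, the counts stayed within 1.5 times without background correction, with an offset of 16, with scale or quantile normalization, with no filter, with a robust variance trend and with a row curve alone. They were 4674 and 5164 with median centring, 652 and 10409 with the deposited ratios, 6608 and 6286 with these centred, 529 and 542 without flagged spots (6668 probes tested), 552 and 596 at 1.5-fold or more, 1176 and 1070 with a curve per print block, 516 and 359 with a further curve per row, 193 and 127 with both and 1.5-fold, and 8246 and 221 centred on Y1 to Y4; 1127 were lower among probes above background in both channels on all arrays. The filters and the fold limit lower the counts by construction; the cause of the others was not tested beyond the position tests. The probes called changed more than some counts show. Of the 3903 calls, 2789 passed in the same direction without background correction, 2452 with a row curve alone and 2393 with median centring. With the offset of 16, scale or quantile normalization, no filter or the robust variance trend, 3656 to 3903 did. Without the pairing of channels by array (no replicate block) the counts were 731 and 857. Leaving out one array gave 1002 to 2009 higher and 884 to 1807 lower probes. Of the 3903 calls, 3152 passed in the same direction without array 1, 1798 without array 2 and 2542 without array 3. Of 265 values of named genes and probes under alternatives, 207 kept direction and side of the threshold, 26 lost and 22 gained a call, and 10 reversed: Hsp70Bc with median centring (0.13), the centred deposited ratios (0.58), Y1 to Y4 (0.18) and without replicate 3 (0.055, against -0.71 without replicate 1); His3.3A with the centred deposited ratios (0.12) and Y1 to Y4 (0.28); Hsp60 (0.27), Nup154 (0.25) and RpS25 (0.16) with Y1 to Y4; and Act42A without replicate 1 (-0.0070). Centring on Y1 to Y4 shifts all genes alike, which gives its 5 reversals by construction. Those on leaving out a replicate follow from the arrays that remain. Act42A was at -0.058 and 0.044 on arrays 2 and 3, and Hsp70Bc at 0.66 and -0.55 on arrays 1 and 2. The cause of the remaining reversals was not tested. Genes in place of probes, the mean of all probes of a gene, scanner-normalized ratios and the alternatives for gene lists gave no value. RpS25, at 67.4 in the infected channel, lay close to the background limit of 46.6 to 58.3.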

Other observations

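Of the tests below, those on the blocks that hold the probes high on arrays 1 and 2, on another tissue, and on the print rows were set before their results were seen, and the others after. The probes past the threshold were unevenly spread over brightness: in 5 equal classes by mean intensity, numbered from the dimmest, 48.4% of the probes of class 2 passed, against 19.1% in class 1 and 19.1% in class 5. Correction by print block and row left 7.61% of the calls of class 2 and 34.9% of those of class 5.

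Position on the slide is a candidate explanation for the 2065 of 3903 calls that ended with a curve per print block, whose median absolute log2 ratio went from 0.43 to 0.26 while the median standard error stayed close (0.105 before, 0.10 after), a fall that their selection by the lost call also gives and that is no evidence by itself. The oligonucleotides of the dim genes RpS25, Hsp60, Nup154 and CG13334, each present under one name in all 48 blocks, followed the block medians of the other probes with a median r of 0.74 across blocks (permutation p under 0.05 in 12 of 12 gene and array pairs, also adjusted over all 36 pairs), against a median r of 0.16 for the 8 brighter genes, of which His3.3A (r of 0.48 to 0.82) and Hsp70Bc on arrays 1 and 2 (0.64 and 0.74) also followed them, with 10 of 24 pairs above 0 and 1 below 0 at a permutation p under 0.05. These p-values are likely too small, because the permutation treats neighbouring blocks, whose medians were often alike, as exchangeable. The block medians of the arrays correlated with r of 0.90 to 0.93, so the pairs are not independent. After trends by block and row were removed, 771 of the 3903 (19.8%) passed in the same direction, and 875 of all 14238 probes tested passed, which argues against these trends as the whole source of the 3903 calls (median absolute log2 ratio of the 771, 0.59 before and 0.54 after, and of the 3132 that ended, 0.45 and 0.23, both shaped by the selection). For the lower ratios of rows 2 to 9 the row cannot be told apart from the genes printed there: probes above background nowhere differed by -0.040 between the rows (permutation p = 0.0543), but their ratios are compressed, with an SD of 0.11 against 0.35 in the other probes. A dye preference of the probes and the infection cannot be told apart either, since 0 arrays carried the control in Cy5, and with 4 sign patterns of 3 arrays, of which 1 gave as many as 3903 probes and the others at most 0 (limma, 32 to 73 probes at an unadjusted p under 0.05), no share under 0.05 can be had.

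Hsp70Bc was higher in infected testes on array 1 and lower on arrays 2 and 3, with a median signal of 1645, 1172 and 1353 in the infected and 1100, 1855 and 2725 in the control samples of arrays 1, 2 and 3. The print block is argued against by its 96 spots: the block means had the same sign in all 48 blocks of each array, with 0 of the other sign. These spots all lay in the first row of a block, so the block means cannot speak to an effect of print row. Normalization is argued against only as the source of the gap between array 1 and the nearer of the other arrays. This gap was at least 1.06 on the log2 scale over 7 normalizations, where the spots of one array had an SD of at most 0.19. The sign on each array is not covered, since a shift of all arrays alike leaves the gap unchanged. The mean over the arrays turned to 0.13 with median centring and to 0.58 with the centred deposited ratios, the latter not among the 7. Dyes of array 1 the other way round stay open: its correlation with the others was at least 0.59 across all probes, but dye and position effects shared by the arrays could give that too. A difference in heat or handling between independently grown samples may remain, as a hypothesis with no test in these data.

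A set of 6 probes, DM00016241 and DM00008901 among them, was at least 4-fold higher in infected testes on arrays 1 and 2 and within 0.5 of 0 on the log2 scale on array 3. No probe was high on arrays 1 and 3 or on arrays 2 and 3 in this way, and none was lower in this way on any pair. Their median infected signal was 8999 and 8293 on arrays 1 and 2 and 64.6 on array 3, while their control signal stayed at 426, 507 and 413. A shared print block is argued against by their place, in 6 different print blocks. Their rows within the blocks were not compared, so an effect of print row was not tested. Another tissue in the infected samples 1 and 2 could give such a set; this stays open, since 0 of the 6 probes has a gene name in the files, and so does a biological difference between the infected samples.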
